A study of Homo sapiens with 6 samples.

How the data were processed

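MicroRNA (miRNA) levels were measured in Flp-In 293 cells, a human embryonic kidney line with a single recombination site for inserting a transgene. Per the labels, the cells stably expressed TRBP, the double-stranded RNA-binding partner of Dicer, in a phospho-mutant or a phospho-mimic form, and 3 samples of each were hybridised to 1 array each. The groups and the replicate numbers were taken from the sample titles, which call the replicates biological. The labels do not say whether replicates came from separate cultures or clones, so the p-values measure only the spread between these samples. The labels give the confluency at harvest differently in 2 places.

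Per the labels' protocols, total RNA was size-fractionated, extended with a poly(A) tail and ligated to a tag, and the tag was stained with Cy5 after hybridisation to a 1-colour microfluidic array from LC Sciences. Each deposited array file holds 3968 spots with a linear intensity, the mean spot density, and per the file headers no background column. The values are not background-subtracted, since the 61 empty spots per array read between 30.7 and 36.5 on average. Of the spots, 353 are controls, and the rest hold 5 spots for each of 723 human miRNAs. The authors also deposited a table of processed intensities, in which the background had been removed and the arrays scaled. Its method, the scanner and the image software are not given in the sources used here. Over 70 bright miRNAs its log2 values correlated with the array files at between 0.997 and 0.999, and the median of its columns lay between 2.0 and 5.0. The ratio of the authors' intensity to the density above the empty spots had a median from 0.682 to 1.79 per array and differed between the dim and the bright miRNAs of an array, and the form of their scaling stays unknown. The authors' design text says that values less than 500 were left out.

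From the array files, spot intensities were background-corrected with normexp (offset 50) in limma, run on the densities alone. The 5 spots of a miRNA were averaged, the arrays were quantile-normalized, values under 32 were set to 32 and log2 was taken. Because of the offset no value lay at that floor. The 72 miRNAs with a mean of at least 500 over the 6 arrays were tested. All 72 were detected on all 6 arrays, detection being a mean density over the empty-spot mean plus 3 SD. Signals below are these normalized intensities. Quantile normalization gives equal values to equal ranks, so some differences between arrays are exactly 0, as for miR-92a, the brightest miRNA on 5 of the arrays.

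The test was limma's moderated linear model (lmFit and eBayes) of phospho-mimic minus phospho-mutant, two-sided, with Benjamini-Hochberg adjustment over the 72 miRNAs and a threshold of 0.05. Confidence intervals are at 95%. Of the 26 miRNA lists fixed before the data were examined, the 18 with at least 2 tested members were tested with fry and with camera, at a preset correlation of 0.01 and with an estimated correlation, and adjusted over the 18. Fry asks whether a list moves one way on balance and does not compare it with other miRNAs. An exact permutation over the 20 labelled splits of the arrays was added, with a smallest two-sided p of 0.1. The let-7 and miR-17~92 lists were taken from published work on TRBP phosphorylation, possibly on these samples, so they are not independent evidence of direction. The named miRNAs are the 5 with the smallest p in each direction, the tested members of let-7 and miR-17~92, the 3 brightest, and the 2 members of each other list with the largest absolute change. The same rule applied to the fit with a replicate block adds the miRNAs that passed there. A planned test of star strands could not be run, because none of the 165 on the array reached the signal filter.

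Both groups carry replicate numbers 1 to 3, and the pairing was checked before the fit with the replicate number as a block was run. The deviations from the group means correlated, across the 72 miRNAs, at 0.81, 0.77 and 0.18 between arrays with the same number, and 5 of the 6 arrays correlated best with their own number. Phospho-mutant 3 correlated at 0.43 with phospho-mimic 2. All 3 correlations exceeded the limit of 0.1 set for treating the numbers as pairs, so blocked values are given where they change a result. This check is weak. The 3 deviations of a group cancel out, so a match of the replicate 1 arrays alone raises the correlations among the other arrays. It therefore does not establish that the numbers mark pairs, least of all for replicate 3. The labels do not state that a number marks a shared day or batch. They do say that 1 sample per group was analysed first and the others later, without naming it. Replicate 1 was assumed to be that sample, so the later arrays below are those of replicates 2 and 3.

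The fits were tested on 200 simulated sets of the 72 miRNAs with the measured pair effects and spread, in which 6 miRNAs changed 2-fold and 6 changed 4-fold. Without the block, limma recovered 8.25% of the 2-fold and 86.8% of the 4-fold changes, with no false call. With the block it recovered 86.9% and 99.4%, and 6.17% of the calls were false. A fall of let-7 by 1 log2 unit was recovered by fry in none of the sets without the block and in 30.5% with it. In all these sets, arrays with the same number shared an identical pair effect. The recoveries and false calls with the block therefore hold only if the numbers mark true pairs, which the labels do not state. Beyond the pair effect, the simulated noise was independent between miRNAs. The measured pair differences of the let-7 members moved together, so the let-7 recovery with the block can be too high.

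Alternatives were cyclic loess, median scaling, no normalization, the authors' intensities, plain subtraction of the empty spots, floors of 1 and 100, other filters, eBayes with a trend, array weights, the replicate block, a block of replicate 1 against the later arrays, the later replicates alone, and each array left out. The median of the spots and combinations of the replicate block with another normalization, a GC correction, another filter or a pair left out were added after seeing the data. Neighbouring miRNA genes were found in a RefSeq gene table of GRCh38.p14, in which 67 of the 72 miRNAs had a locus. The array files name no genome build, so no coordinates are given. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.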

Results

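The levels of 723 human miRNAs were measured on 6 arrays, 3 from cells expressing phospho-mutant TRBP and 3 from cells expressing phospho-mimic TRBP. TRBP binds Dicer, the enzyme that cuts miRNA precursors, and the comparison asks whether its phosphorylation state alters miRNA levels. Between 210 and 237 miRNAs were detected per array, 174 on all 6, and the number of arrays limits the precision. The brightest miRNAs in these cells were miR-92a, miR-20a and let-7a. The signal of miR-92a was 22881 ± 3601 in phospho-mutant cells (SD, n = 3) and 24959.5 on all 3 phospho-mimic arrays.

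In phospho-mimic cells, miR-218, miR-20b and miR-15a were higher than in phospho-mutant cells, and miR-923, miR-197, miR-125a-5p and miR-128 were lower, when arrays with the same replicate number were compared as pairs. Each of the 7 had the same direction in all 3 pairs, and the differences reached 3.30-fold for miR-218 and 2.38-fold for miR-923. The paired fit that selected the 7 favours miRNAs whose pairs agree, so the shared direction is not separate evidence. Of these, miR-15a, which is encoded beside miR-16 and represses BCL2, and miR-20b, of the miR-106a~363 cluster, belong to families linked to the cell cycle and survival, and miR-128 is enriched in brain. The probe named miR-923 has since been assigned to a fragment of 28S ribosomal RNA. None of the 7 passed the planned limma test without pairing.

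Among the higher ones, miR-218 (UUGUGCUUGAUCUAACCAUGU) had a signal of 1704 ± 811 in phospho-mutant and 5289 ± 1575 in phospho-mimic cells (SD, n = 3). Its log2 change was 1.72 ± 0.38 (SE with the replicate block), with a limma adjusted p of 0.103 without the block and 0.0358 with it. The signal of miR-20b (CAAAGUGCUCAUAGUGCAGGUAG) was 4328 ± 2046 and 9026 ± 2500 (SD, n = 3), a log2 change of 1.13 ± 0.21 with adjusted p of 0.301 and 0.0319 in limma. For miR-15a (UAGCAGCACAUAAUGGUUUGUG) the signal was 1209 ± 510 and 2413 ± 1238 (SD, n = 3), and the log2 change of 0.93 ± 0.20 had limma adjusted p of 0.639 and 0.0332. Single arrays moved it, to 0.48 without phospho-mutant 3 and 1.48 without phospho-mimic 3, and the change of miR-218 was 1.13 without pair 3. The groups did not overlap for miR-218, whereas those of miR-20b and miR-15a did. The ± of these 3 changes is the SE with the block, and without it the SE was 0.46 for miR-218, 0.42 for miR-20b and 0.56 for miR-15a. The log2 change of miR-16, encoded beside miR-15a and also beside miR-15b, was 0.0027 ± 0.26 (SE without the block), so it did not share the rise.

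Among the lower ones, miR-923 (GUCAGCGGAGGAAAAGAAACU) had a signal of 1268 ± 406 in phospho-mutant and 517 ± 87.7 in phospho-mimic cells (SD, n = 3), a log2 change of -1.25 ± 0.20. For miR-197 (UUCACCACCUUCUCCACCCAGC) the signal was 1229 ± 246 and 545 ± 142 (SD, n = 3), a log2 change of -1.18 ± 0.21. For miR-125a-5p (UCCCUGAGACCCUUUAACCUGUGA) it was 4984 ± 490 and 2612 ± 112 (SD, n = 3), a log2 change of -0.93 ± 0.19. For miR-128 (UCACAGUGAACCGGUCUCUUU) it was 2805 ± 225 and 1498 ± 159 (SD, n = 3), a log2 change of -0.91 ± 0.19. All 4 had a limma adjusted p of 0.103 without the block, and 0.0319, 0.0319, 0.0332 and 0.0332 with it, and the groups did not overlap for any of them. The ± of these 4 log2 changes is the SE with the block. Without the block the SE was 0.33, 0.30, 0.23 and 0.23 in the same order.

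**Figure D1:**
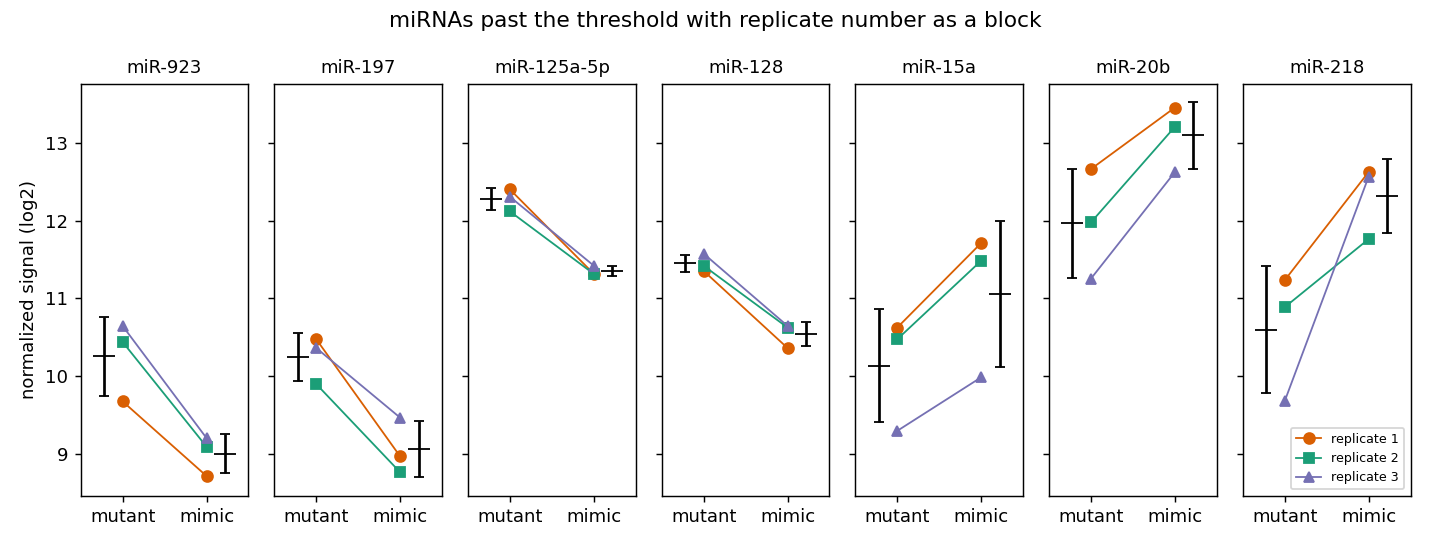
Normalized log2 signal (vertical axis) of 7 miRNAs on each array, with a line joining the phospho-mutant and phospho-mimic arrays of 1 replicate number and black bars for the group mean ± SD (n = 3). All 3 lines run downward for miR-923, miR-197, miR-125a-5p and miR-128 and upward for miR-15a, miR-20b and miR-218, and the steepest is replicate 3 of miR-218 with a difference of 2.89.

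Over all 72 tested miRNAs, limma without the block found 0 past the adjusted threshold, the smallest adjusted p being 0.103, and 8 at an unadjusted p under 0.05 (3 higher and 5 lower) against 3.6 from chance. With the replicate block 7 passed (3 higher and 4 lower) and 16 had an unadjusted p under 0.05. The log2 change was positive for 34 miRNAs and negative for 38. Quantile normalization gives all arrays the same distribution, so this near balance was largely set in advance. A change shared by most miRNAs could not be seen in this fit. Without normalization 58 were positive and 14 negative, with a median of 0.41, but differences in brightness between arrays then remain. For 8 miRNAs the groups did not overlap, where chance gives 10%, or 7.2. In all 3 pairs or in none of them, 35 were higher in phospho-mimic, against 18 from chance. A tie, a difference of exactly 0, counted as not higher. The 35 therefore include miRNAs with a tied pair, such as miR-103, and leave out positive ones with a tie, such as miR-17. Fewer than 35 had 1 sign in all 3 pairs, so the excess over 18 is overstated. The other miRNAs with the smallest p did not pass either fit. They were let-7g, miR-18b and miR-7, with log2 changes of 0.97 ± 0.30, 0.65 ± 0.32 and 1.45 ± 0.80 (SE without the block), and miR-27b, with -0.69 ± 0.27. The value of miR-7 was 2.33 without phospho-mutant 1 and 0.91 without phospho-mutant 3, that of miR-18b was 0.39 without phospho-mimic 2, and that of miR-27b was -0.42 with median scaling. The blocked calls depended on the scaling and the filter, since limma with the block passed 0 miRNAs after cyclic loess, 0 after median scaling, 9 on the authors' intensities (let-7g, miR-195 and miR-99b besides 6 of the 7), 2 after a GC trend was removed, 8 with a filter of 500 in 1 group, 11 with a filter of 100, and 2 with all miRNAs tested (miR-101 and miR-15b*, none of the 7). They also depended on single pairs, with 0, 3 and 0 passing when pair 1, pair 2 or pair 3 was left out, and 0 passed when the block parted only replicate 1 from the later arrays (smallest adjusted p 0.0523, 12 at an unadjusted p under 0.05). Without the block, limma passed 4 miRNAs when phospho-mutant 1 was left out (let-7i higher, and miR-125a-5p, miR-128 and miR-923 lower) and 11 with array weights, of which 4 were higher, let-7g among them, and 7 lower.

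The let-7 family, which restrains growth and represses RAS and LIN28, showed no detectable shift as a group. In this design a simulated fall of 1 log2 unit was recovered in 0% of sets without the block and 30.5% with it. The simulated noise was independent between miRNAs, so the 30.5% can be too high for the let-7 family. Of its 9 members on the array 7 were tested, none passed limma over all miRNAs or adjusted over the list alone, and the mean log2 change was -0.18 (fry adjusted p = 0.952, exact permutation p = 0.9). The negative values were those of let-7e (-0.69 ± 0.43), let-7a (-0.48 ± 0.34), let-7d (-0.35 ± 0.43), let-7b (-0.34 ± 0.52), let-7f (-0.22 ± 0.30) and let-7c (-0.14 ± 0.51), each with its SE. The value of let-7g was 0.97 ± 0.30, with a signal of 1013 ± 263 in phospho-mutant and 1966 ± 407 in phospho-mimic cells (SD, n = 3). Its sequence (UGAGGUAGUAGUUUGUACAGUU) differs from that of let-7a (UGAGGUAGUAGGUUGUAUAGUU) at 2 positions, and its limma adjusted p was 0.158, or 0.0798 with the replicate block, while it passed with array weights and with the block on the authors' intensities. The family mean was -0.88 in the replicate 1 pair and 0.22 and 0.13 in the others. Without phospho-mutant replicate 1 it was 0.33, over 8 members, since let-7i then also passed the signal filter. It was also positive with array weights, at 0.16, and in the later replicates alone, at 0.16, and the values of let-7b, let-7c, let-7d and let-7f were positive in both.

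The miR-17~92 cluster, a growth-promoting polycistron, had positive values without passing fry. Of 6 members on the array 5 were tested, with log2 changes of 0.51 ± 0.36 for miR-19b, 0.37 ± 0.36 for miR-18a, 0.33 ± 0.33 for miR-17, 0.30 ± 0.35 for miR-20a and 0.14 ± 0.24 for miR-92a (SE). The value of miR-92a was negative with cyclic loess (-0.10), median scaling (-0.12) and, relative to the median shift, no normalization (-0.20). The cluster mean was 0.33 (fry adjusted p = 0.542, exact permutation p = 0.4), and the pair means were 0.80, 0.15 and 0.046. It was 0.072 without phospho-mutant 1, 0.50 without phospho-mutant 2, 0.085 in the later replicates alone and 0.10 with array weights, and the fry adjusted p lay between 0.0743 and 0.912 over the alternatives. With miR-19a admitted by a filter of 500 in 1 group it was 0.61, and 1 member, miR-19a, then passed adjusted over the list alone. That filter uses the groups, and miR-19a entered only through its phospho-mimic signal, which favours a rise. The filter of 100, which does not use the groups, also gave a mean of 0.61. With the replicate block too, limma over all miRNAs passed miR-19a at that filter (adjusted p = 0.0016) and at one of 100 (0.00576), but not with all miRNAs tested (0.0555). In that last setting without the block, camera at the preset correlation passed the cluster (adjusted p = 0.0208), its paralogues (0.0111), the miR-29 family (0.0208) and the miR-23/27/24 clusters (0.0208), and with an estimated correlation none of them (0.855, 0.569, 0.855 and 0.855). With the block, camera at the preset correlation passed these lists, the miR-130 to miR-152 list and the fragment probes with all miRNAs tested, and none with an estimated one (adjusted p = 0.793 for each). None of the 5 otherwise tested passed limma over all miRNAs or adjusted over the list alone. In the paralogue clusters, miR-106a~363 and miR-106b~25, all 6 tested members had positive values with a mean of 0.48 (fry adjusted p = 0.246). Of these miR-20b passed with the replicate block, and the value of miR-18b was 0.65 ± 0.32.

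**Figure D2:**
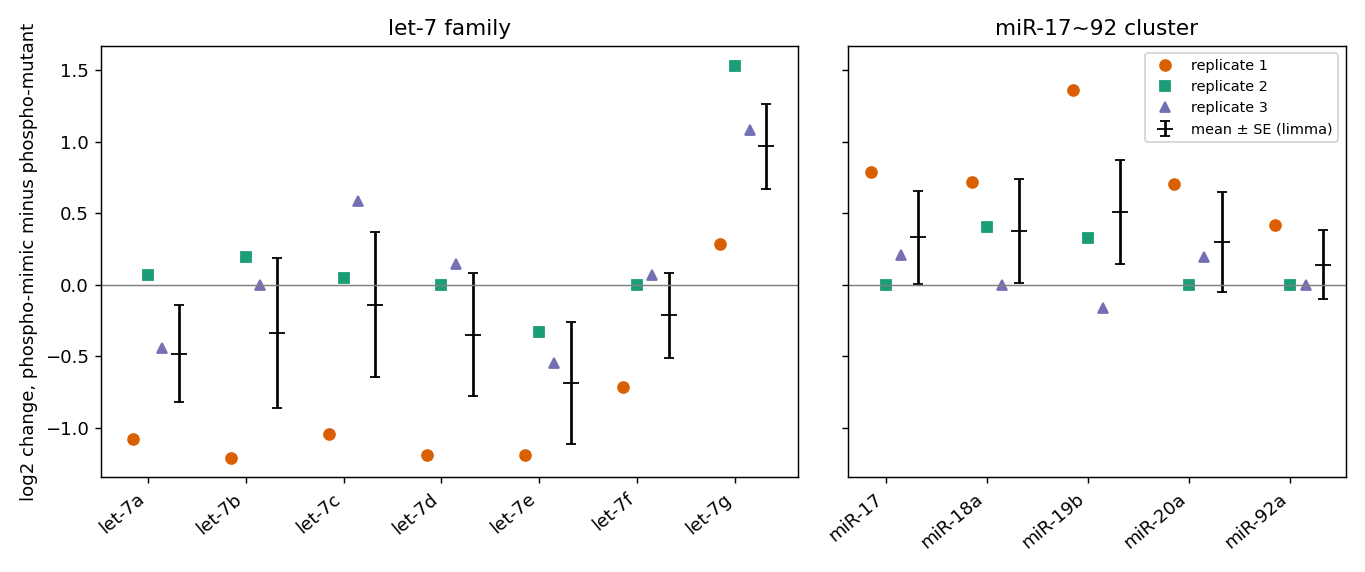
Log2 change (phospho-mimic minus phospho-mutant, vertical axis) of the tested let-7 and miR-17~92 members in each replicate pair, with black bars for the limma mean ± SE over 3 arrays per group. In let-7, replicate 1 gave the lowest value for each of the 7 members, and let-7g alone has 3 positive values. In miR-17~92, replicate 1 gave the highest value for each of the 5.

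The tested members of the miR-99/100 and miR-125 families, miR-125a-5p, miR-99b and miR-125b, had negative values, and their shift passed fry without the block but not camera or fry with the block. The 3 members had a mean log2 change of -0.63, with pair means of -0.74, -0.53 and -0.62, and values of -0.93 for miR-125a-5p, -0.78 for miR-99b and -0.19 for miR-125b. The adjusted p was 0.0234 with fry and 0.108 with fry and the replicate block, and with camera it was 0.110 at the preset and adjusted p = 0.612 with an estimated correlation. The exact permutation p was 0.1, the smallest possible. With dimmer members admitted the mean was -0.42 with a filter of 100 (1 of 4 positive) and -0.28 with all 5 members tested (2 positive). The fry call was also lost with median scaling (adjusted p = 0.0743), no normalization (0.854), all miRNAs tested (0.223), a filter of 100 (0.164), the median of spots (0.0723), the later replicates alone (0.224) and the block of replicate 1 against the later arrays (0.0522). Leaving out 1 array kept it only without phospho-mimic 2 (adjusted p = 0.0180). The miR-26 family had a mean of -0.23 over 2 members, miR-26b at -0.35 ± 0.29 and miR-26a at -0.12 ± 0.31 (SE), with a fry adjusted p of 0.0383, 0.141 with the block, and 0.741 with camera (adjusted p = 0.802 with an estimated correlation). Neither member was near the limma threshold (unadjusted p = 0.27 for miR-26b and 0.71 for miR-26a). Their deviations ran opposite to each other (estimated correlation -0.97) and so cancel in the mean, which makes the family mean look precise. The fry call of the family was lost in the same settings, with a fry adjusted p of 0.229, 0.947, 0.141, 0.0943, 0.0723, 0.130 and 0.123 in that order, and leaving out 1 array kept it only without phospho-mutant 1 (0.0200).

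No other list passed fry, with adjusted p between 0.229 and 0.995 for those named here. Positive means were those of the miR-15/16 family (0.43 over 4, with miR-15a at 0.93, miR-195 at 0.68, miR-15b at 0.10 and miR-16 at 0.0027), miR-21 and miR-31 (0.56, with 0.71 and 0.41) and miR-221 with miR-222 (0.53, with 0.89 and 0.17). All 4 tested members of the miR-23/27/24 clusters had negative values (mean -0.37), among them miR-27b at -0.69 and miR-23b at -0.42. The probes since assigned to fragments of ribosomal and other RNAs had a mean of -0.93, with miR-923 at -1.25 and miR-768-5p at -0.61. The list named GC-rich probes had one of -0.88, with miR-923 again and miR-638 at -0.50. By its sequence miR-923 is not GC-rich (47.6% GC, against 80% for miR-638), so this mean does not describe GC-rich probes. The neural miRNAs had a mean of -0.29, from miR-128 at -0.91 and miR-132 at 0.32. Single arrays moved these means: miR-221 with miR-222 to 1.09 without phospho-mimic 2 and 0.044 without phospho-mimic 3, miR-15/16 to 0.22 without phospho-mimic 1, 0.23 without phospho-mutant 3 and 0.65 without phospho-mimic 3. The signal filter was applied anew each time, so part of a move can come from a change in the tested members of a list. Without phospho-mutant 3, that of miR-21 and miR-31 was 0.33 and that of the miR-23/27/24 clusters -0.21, and the neural one was -0.15 without phospho-mimic 2 and -0.17 without phospho-mutant 1. The change of miR-21 was 0.036 without phospho-mutant 3 and 1.36 without phospho-mutant 1, and that of miR-31 was 0.10 without phospho-mutant 1. Scaling moved some means as well. With median scaling the neural mean was -0.032 (-0.13 with cyclic loess), that of the GC-rich probes -0.54, that of the miR-23/27/24 clusters -0.21, with 1 of the 4 members positive, and that of miR-221 with miR-222 0.87. With all miRNAs tested the GC-rich mean was -0.10, the fragment mean -0.45 and the neural mean -0.011. Smaller means were found for miR-103 with miR-107 (-0.21, with -0.27 and -0.14), the mirtron and short-hairpin list (0.17, with miR-320 at 0.38 and miR-877 at -0.044), the miR-181 family (-0.068, with miR-181a at -0.38 and miR-181b at 0.24), the miR-10 and miR-196 families (0.067, with miR-196a at 0.36 and miR-10a at -0.16), the miR-30 family (-0.062, with miR-30a at 0.38 and miR-30d at -0.34) and the miR-130, miR-301, miR-148 and miR-152 families (-0.031, with miR-454 at -0.42 and miR-148a at 0.22). For the latter list, and for miR-10 with miR-196, the median and the mean differed in sign or the median was 0. The means of the miR-30, miR-103 with miR-107, miR-130 to miR-152, miR-181 and miR-10 with miR-196 lists turned sign under at least 1 other scaling. Adjusted over the list alone, 1 member passed limma in each of the miR-99/100 and miR-125, neural, fragment and GC-rich lists, namely miR-125a-5p, miR-128, miR-923 and miR-923. With the replicate block the same number passed in the neural, fragment and GC-rich lists, 2 in the miR-99/100 and miR-125 list (miR-125a-5p and miR-99b), 2 in the miR-15/16 family (miR-15a and miR-195), and 1 each in the miR-23/27/24 clusters (miR-27b) and the paralogue clusters (miR-20b).

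The replicate 1 arrays shared a difference from most of the later arrays. Replicate 1 against the later arrays took 46.4% of the variation over the 72 miRNAs, the TRBP form 23.5%, and a term of this size takes 20% by chance. That replicate 1 was the sample analysed first is an assumption, since the labels do not name it. The log2 signals of phospho-mutant 1 correlated across miRNAs at 0.90 with phospho-mimic 1, at 0.86 with phospho-mimic 3, at 0.75 with phospho-mutant 2 and at 0.76 with phospho-mutant 3, and miRNAs are not independent replicates. Phospho-mimic 1 correlated at 0.86 with phospho-mimic 2 but at 0.93 with phospho-mimic 3, so on this measure it did not stand apart from the latter. With the group in the model, 1 miRNA passed limma's adjusted threshold between replicate 1 and the later arrays. It was miR-195, which was 3.17-fold higher on the replicate 1 arrays (adjusted p = 0.00748). The difference was not confined to miR-195. More miRNAs had an unadjusted limma p under 0.05 here than in the TRBP comparison with or without a block. The next were miR-130b and miR-181a, lower on the replicate 1 arrays (limma adjusted p = 0.0720 for each).

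**Figure D3:**
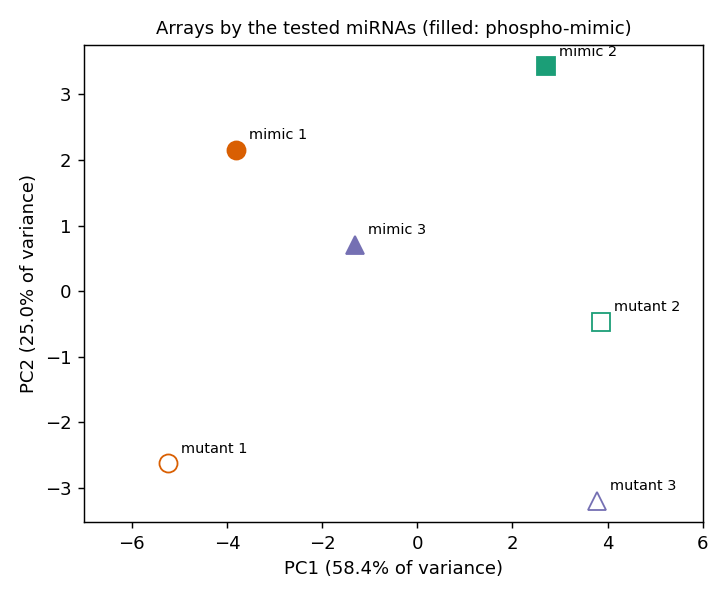
First and second principal components of the log2 signal of the 72 tested miRNAs, 1 point per array, filled for phospho-mimic and open for phospho-mutant, with circles, squares and triangles for replicates 1, 2 and 3. The first axis holds 58.4% of the variance and places both replicate 1 arrays at its lower end, with phospho-mimic 3 between them and the other later arrays.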

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

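The rule that singled out the following signal, a control probe more than 5-fold brighter on a phospho-mimic array than on every phospho-mutant array, was chosen after the control probes were seen. The control probe a-PUC2MM2d, which reads no human miRNA by its name and type, had a mean density of 1240.0 on phospho-mimic 1 and at most 86.0 on the phospho-mutant arrays, a 14.4-fold difference confined to that array, since the other phospho-mimic arrays read 37.5 and 75.4. All 4 of its spots on that array lay between 1056 and 1473.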

How the results depend on the processing

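The median of the spots and the combinations of the replicate block with another scaling, a GC correction, another filter or a pair left out were chosen after seeing the data. The miRNAs past limma's adjusted threshold, 0 higher and 0 lower, numbered 3 and 4 with the replicate block, 4 and 7 with array weights, and 0 and 2 (miR-125a-5p and miR-503, lower) with all 723 miRNAs tested. With the block they were 5 and 4 on the authors' intensities, 1 and 1 after GC correction, 3 and 0 without pair 2, and 4 and 4, 6 and 5, and 2 and 0 with a filter of 500 in 1 group, one of 100 and none. Leaving out 1 array gave 0 to 1 higher and 0 to 3 lower, all 4 without phospho-mutant replicate 1 (let-7i higher, miR-125a-5p, miR-128 and miR-923 lower). The other settings gave 0. Of the lists other than let-7 and miR-17~92, 2 passed fry, and 0 did with the replicate block, the block of replicate 1, median scaling, no normalization, no filter, a filter of 100, the later replicates alone or the median of spots, and with the block after GC correction, without a pair or with those filters. The number was 1 with a filter of 2000, 4 with array weights, and, with the block, 1 after cyclic loess, 3 after median scaling and 4 on the authors' intensities. Leaving out 1 array gave 0 to 2.

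The cause of the sign changes was not tested. With cyclic loess, with or without the block, they were the miR-30 family (0.0020), the miR-130 and miR-301 list (0.14), the miR-10 and miR-196 list (-0.10), miR-92a (-0.10) and miR-107 (0.0066). With median scaling, with or without the block, they were the miR-30 family (0.087), the miR-103 and miR-107 list (0.0065), the miR-130 and miR-301 list (0.24), the miR-181 family (0.11), the miR-10 and miR-196 list (-0.071), miR-92a (-0.12), the miR-30d log2 change (0.0092), miR-107 (0.055), miR-454 (0.049) and miR-877 (0.027). No normalization moved the median of all miRNAs by 0.44, and relative to that shift they were the miR-30 family shift (0.0026), the miR-130 and miR-301 list (0.16), the miR-181 family (0.024), the miR-10 and miR-196 list (-0.16) and miR-92a (-0.20). On the authors' intensities, with or without the block, it was the miR-130 and miR-301 list (0.078). Array weights turned the let-7 family (0.16), let-7b (0.16), let-7c (0.38), let-7d (0.059), the let-7f log2 change (0.0069), miR-148a (-0.12) and miR-877 (0.28). The later replicates alone, and equally the block without pair 1, turned the let-7 family (0.16), let-7b (0.090), let-7c (0.28), let-7d (0.053) and let-7f (0.039). With or without the block, a filter of 500 in 1 group turned the miR-130 and miR-301 list (0.019), no filter turned the miR-130 and miR-301 list (0.16) and the miR-181 family (0.12), one of 100 turned the miR-130 and miR-301 list (0.17), the miR-181 family (0.14) and the mirtron list (-0.0033). The median of spots turned the miR-181 family (0.0034). With the block, GC correction turned the miR-10 and miR-196 list (-0.011), miR-877 (0.32) and miR-638 (0.17), leaving out pair 2 the miR-130 and miR-301 list (0.022) and miR-877 (0.044), and leaving out pair 3 the miR-30 family (0.084), the miR-130 and miR-301 list (0.091), miR-26a (0.030), miR-181b (-0.011) and miR-222 (-0.20).

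Leaving out 1 array at a time turned the let-7 family (-0.47 to 0.33), let-7b (-0.77 to 0.26), let-7c (-0.43 to 0.39), let-7d (-0.71 to 0.10), let-7f (-0.38 to 0.040), miR-20a (-0.036 to 0.53), miR-148a (-0.12 to 0.52), miR-222 (-0.36 to 0.70), miR-320 (-0.0062 to 0.60), miR-877 (-0.42 to 0.43), the miR-30 family (-0.27 to 0.14), the miR-103 and miR-107 list (-0.52 to 0.081), the miR-130 and miR-301 list (-0.26 to 0.14), the miR-181 family (-0.32 to 0.16), the miR-10 and miR-196 list (-0.013 to 0.21), miR-107 (-0.47 to 0.16), miR-26a (-0.43 to 0.044), miR-30d (-0.72 to 0.020), the mirtron list (-0.017 to 0.38) and miR-181b (-0.056 to 0.39), given as lowest and highest value. Let-7 had a fry adjusted p between 0.148 and 0.998 under every setting run, and miR-17~92, always positive, between 0.0743 and 0.912. The 7 miRNAs called with the block had 1 direction in every setting that measured them. A floor of 1 changed nothing, because no value lies that low. The star-strand test was not run, and a list with under 2 members left has no value. Because the signal filter was applied anew in each setting, a list can hold other members than in the main fit. The filter on signal limits the test to 72 of 723 miRNAs, while 174 were detected on all 6 arrays and 143 tested with a filter of 100. The other extreme, detection on no array, held for 439.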

Other observations

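The tests of the scaling, of the spike probes, of GC content on the replicate 1 arrays and of genomic clusters, and the miRNAs named in the next 2 paragraphs, were chosen after the results were seen.

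Several miRNAs below the signal filter were bright on some arrays. The signal of miR-451, a red-cell miRNA, was 816 on phospho-mutant 2 and 276 on phospho-mimic 2, and between 54.2 and 57.1 on the other 4 arrays, and all of its 5 spots were bright on the former arrays. The let-7 relative miR-98 read 603 on phospho-mutant 1 and 195 on phospho-mimic 1, and at most 73.4 on the later arrays. Likewise miR-196b read 725 and 1048 on the replicate 1 arrays and at most 251 on the others. The value of miR-875-5p on phospho-mutant 3, 1175, came from 1 spot of 5, which read 3766 while the other spots of that array read at most 34.2.

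Some dim signals read higher on the phospho-mimic arrays, without passing limma on all 6 arrays when the replicate block was not used. The signal of miR-19a, a miR-17~92 member, was 167, 154 and 88.8 in phospho-mutant and 816, 577 and 322 in phospho-mimic cells, and that of let-7i was 480, 265 and 257 against 588, 588 and 627. With all 723 miRNAs tested, their limma adjusted p was 0.393 and 0.619, and with a filter of 500 in 1 group 0.0908 and 0.219, and let-7i passed when phospho-mutant 1 was left out. With the replicate block the limma adjusted p was 0.0555 and 0.504 with all miRNAs, and 0.0016 and 0.0631 with that filter. The filter of 500 in 1 group uses the groups, and both entered it only through their phospho-mimic signal, which favours a rise. Other dim signals read lower on the phospho-mimic arrays. The signal of miR-574-5p was 627, 197 and 322 in phospho-mutant and 148, 138 and 175 in phospho-mimic cells, and that of miR-34a was 303, 499 and 588 against 296, 234 and 215. Across all 723 miRNAs, 1 was detected on all phospho-mimic arrays and no phospho-mutant array. That was miR-155, at densities of 87.5, 64.9 and 85.3 against detection limits between 35.6 and 42.9, with a limma adjusted p of 0.153 when all miRNAs were tested. No tested member was found among the miR-29, miR-34 and miR-200 families, miR-143 and miR-145, the pluripotency clusters, or the blood, muscle and liver miRNAs. Their brightest members were miR-29a (413), miR-34a (356), miR-200c (176), miR-145 (60.2), miR-371-5p (61.9), miR-486-5p (313), miR-133a (63.3) and miR-122 (56.8), and the brightest star strand was miR-505* (293).

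Other splits of the arrays were counted for each number of calls. Without the block the real split gave 0 miRNAs past the adjusted threshold, all 10 splits gave as many, and the highest other gave 5. That split set phospho-mutant 1, phospho-mimic 1 and phospho-mimic 3 against the rest and called 20 miRNAs at unadjusted p, which points to a structure of the samples. At unadjusted p the real split gave 8, 2 of the 10 splits gave as many, and the highest other gave 20. With the replicate block, 1 of the 4 splits that part all 3 pairs, the real one, gave 7, and the highest of the others, which mix the TRBP forms, gave 0. These splits are too few for a share under 0.05.

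The 7 miRNAs that passed with the replicate block could owe the size of their change to GC content or to the scaling. Taking out a per-array GC trend left a median of 0.926 of the log2 change (lowest of the 7, 0.789), and over 3 other scalings the lowest median was 0.896 (lowest of the 7, 0.715), and without normalization it was 0.618 (lowest 0.326), or 0.901 (lowest 0.792) relative to the median shift of 0.44, which argues against either as the whole source of the sizes. The calls were not kept: 2 of the 7 passed after the GC correction, and 0 after cyclic loess (smallest adjusted p 0.0573) and median scaling (0.0749), while the median SE of the 7 went from 0.204 to 0.207, 0.204 and 0.182. Across the 72 miRNAs the log2 change correlated with GC content at a Pearson r of -0.29 (permutation p = 0.0121, adjusted over 2 relations 0.0242) and a Spearman rho of -0.21 (permutation p = 0.0669, adjusted 0.0669), and miRNAs are not independent replicates. The TRBP form and differences between clonal lines stay open and were not tested.

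The separation of the replicate 1 arrays, from which phospho-mimic 3 stood less far apart, may come from the hybridisation or staining. All 5 perfect-match spike probes, which read no cell RNA, lay outside the range of the later arrays on both replicate 1 arrays, between 1.33-fold and 1.92-fold higher in density before normalization. Not all bright control probes followed. Ctr07-2P and Ctr09-2P read lowest on phospho-mutant 1 (2901 and 9656), and on phospho-mimic 1 (11135 and 23934) lay within the later arrays' range. Quantile normalization would remove a uniform gain, so the spikes do not show that it produced the separation. The share of variation was 46.8% after a GC trend was taken out, against 46.4% before, which argues against GC content as the whole source, although the difference between replicate 1 and later arrays went with GC content across the 72 miRNAs by rank (Spearman rho -0.37, permutation p = 0.0013, adjusted over 2 relations 0.0026; Pearson r -0.22, permutation p = 0.0663). The signal of miR-34c-3p, which did not pass (limma adjusted p = 0.0872), was 4337 on phospho-mutant 1 and 1261 on phospho-mimic 1, but also 659 on phospho-mimic 3. Differences in the cells stay open, and no biological explanation was tested.

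Neighbouring miRNA genes differed less from one another in their change than random pairs of miRNAs. Over 40 pairs with loci within 10 kb, the mean absolute difference in log2 change was 0.285 against 0.606 for shuffled values (permutation p = 0.00020), and over the 26 of these with dissimilar sequences, more than 6 edits apart, it was 0.258 against 0.606 (permutation p = 0.00060). Probes that read each other's targets would not directly make a dissimilar pair alike. However, miR-19b and miR-92a were each set against several probes of similar sequence, such as miR-17 and miR-20a. Cross-reading among those would repeat 1 agreement over several pairs, while the shuffling treated the miRNAs as independent. Over 51 pairs outside clusters with similar sequences the mean difference was 0.463 against 0.604 (permutation p = 0.0619), so cross-reading is not excluded. A shared primary transcript could also give the result, but primary transcripts were not measured here, so that hypothesis stays open. An example with dissimilar sequences is miR-99b, let-7e and miR-125a-5p (-0.78, -0.69 and -0.93), whereas miR-20b and miR-92a, also dissimilar, differed by 0.994, and the pairs share miRNAs. The same test on replicate 1 against the later arrays gave 0.613 against 0.862 (permutation p = 0.0819), and whether TRBP form or clone set the transcript levels was not tested.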
